A study of Homo sapiens with 32 samples.

How the data were processed

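The samples were 32 libraries of poly-A selected RNA from the human cell lines MCF10A and hTERT RPE-1, in 16 groups of 2 libraries. Knockout lines had been made with lentiviral CRISPR-Cas9 and grown from single cells, and drugs were given 1 h before irradiation and kept until collection. The series text describes 3 experiments. The assignment of libraries to these 3 parts was taken from it and from the naming of the samples. All 32 columns of both deposited tables were matched to a sample.

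The first deposited table holds estimated counts, which the authors made per gene and library and which were not normalised: between 96 and 97.3% of the values of a library are whole numbers and the rest have decimals. The second deposited table holds FPKM values, which the authors scaled per kilobase and by library size. The submitters' processing notes name bcl2fastq, FastQC, STAR, Cuffnorm and DESeq2 without versions or roles, and the genome build hg19. The annotation version is not given in the sources used here. Coordinates are those of the count table on hg19. Its intervals can span several genes, as for IFIT1 and IFIT2, so a printed interval may be wider than the gene. Its starts count from 0 and are printed plus 1, because gene lengths equalled those of a reference annotation for 26265 of 56089 matched genes if starts count from 0 and for 327 if from 1.

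Estimated counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, which left 15190, 16632 and 15469 of 60332 genes in parts 1, 2 and 3. All libraries of a part were fitted together with TMM factors by edgeR 4.0.16 (robust quasi-likelihood F test, two-sided), with group as the only term. The parts share no group and were fitted apart. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called, and is said to rise or fall, at an adjusted p below 0.05. The common biological coefficient of variation was 0.187 in part 1, 0.0361 in part 2 and 0.0345 in part 3, with 7, 6 and 3 residual degrees of freedom. CPM are counts scaled by library total and TMM factor, and log2 CPM use a prior count of 2. A value after ± is the standard error beside a log2 fold change and the SD of 2 libraries beside a CPM or list level. The standard error was computed from the fold change and the F statistic.

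Before the data were examined, 18 gene lists, the comparisons, the tests, the rule for named genes and the alternatives were fixed. The lists are interferon-stimulated genes, interferons and T-cell chemokines, antigen presentation and IFN-gamma genes, nucleic acid sensing genes, NF-kB and SASP inflammatory genes, p53 target genes, G2-M genes, G1-S and replication genes, histone genes with polyadenylated transcripts, epidermal differentiation genes, basal and luminal epithelial markers, mesenchymal and extracellular matrix genes, immune and blood cell markers, cholesterol biosynthesis genes, integrated stress and unfolded protein response genes, hypoxia and glycolysis genes, and mitochondrially encoded genes. None of the 15 mitochondrially encoded genes is in the tables (0 found), so that list gave no result. The other 17 were tested in 18 comparisons with gene calls and 7 at list level only, with camera of limma 3.58.1 on voom values at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 17 lists. The same test with an estimated correlation was an alternative fixed in advance. Its adjusted p stands beside each call of a list that is lost with it, and a call printed with 1 camera p held with both. With an estimated correlation the interferon-stimulated call held for ATRi in the DKO, for the DKO with ATRi against XRCC4 KO and against WT, and for the difference of the ATRi effect. The text gives a list's median log2 fold change, and also the median with members at 0 counts in a group set to their bound where that differs.

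The rule for named genes took, for each comparison, the targeted genes, 21 anchor genes of the interferon, p53, inflammatory and cell cycle responses, up to 3 called members per list and direction with the largest change, and the 5 called genes per direction with the largest change among those with a mean of at least 1 CPM and no overlap between the groups. Genes without a regular symbol were left out of the last set, and the text leaves out some genes for length. The levels of 1 targeted gene and of some list members are not reported here. A fold against a group at 0 counts was computed against a floor of 3 counts over the group and is given as "at least". Such floors cover counting error only, and estimated counts are not counts of independent molecules.

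Total counts per library ran from 5590061 to 18585999. The spread between the 2 libraries of a group was set against counting error with a chi-square per gene, over genes with at least 20 counts per pair. With 2 libraries per group no single-value permutation test can reach 0.05, so no other splits of the samples were counted, and p-values rest on the spread pooled over a part. The functions were tested on simulated data drawn from the mean of each gene over a part and its fitted dispersion: of 100 genes changed 2-fold edgeR recovered 48, 89 and 88 in parts 1, 2 and 3, and of 100 changed 4-fold 88, 99 and 98. Of the calls, 4.17, 4.02 and 7.63% were genes left unchanged. These data gave all groups the same spread and drew libraries independently, so the shares do not measure false calls in the real libraries.

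The alternatives were a replicate block, DESeq2 1.42.0, RLE size factors, no filter on low counts, a filter of 1 CPM in 2 libraries, a fit of only the libraries compared, an absolute log2 fold change of at least 1, leaving out each library, and limma on the FPKM values (minimum 1, pseudocount 1 or 0.1). On the deposited FPKM the median log2 fold change of all genes lay between -0.56 and 0.71, and with edgeR between -0.05 and 0.03. Counts of genes higher and lower from FPKM carry that shift. Without a filter that median was 0.14 for the DKO with ATRi against XRCC4 KO and 0.18 for RPE-1 p53 KO against WT, and with the filter 0.03 for each. The direction of each list's median was checked under the scalings, a check chosen after the data were seen, and is given in parentheses where it turns. The analysis used R 4.3.3 and Python 3.11.15.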

Results

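The series measured polyadenylated RNA in 32 libraries from 16 groups of 2 libraries each, in 3 parts. MCF10A is a non-transformed human breast epithelial line, and hTERT RPE-1 is a human retinal pigment epithelial line immortalised with telomerase. Irradiated cells received 10 Gy. Part 1 held MCF10A cells that were untreated, irradiated with vehicle (DMSO) and collected after 3 or 5 days, or irradiated with a CDK1 inhibitor (CDK1i) for 5 days. It also held irradiated cGAS, STING and XRCC4 knockout (KO) cells at 5 days. No knockout cells were measured without irradiation in any part. The labels name DMSO only for the irradiated WT groups of part 1, and no vehicle for its untreated or knockout groups or for the groups without ATRi in part 2. Part 2 held irradiated MCF10A cells at 3 days: wild type (WT), p53 KO, XRCC4 KO without and with an ATR inhibitor (ATRi), and XRCC4 p53 double knockout (DKO) without and with ATRi. Part 3 held RPE-1 cells irradiated with ATRi for 3 days: WT, a group labelled WT cGAS, and p53 KO. XRCC4 is a component of the end-joining ligase complex, cGAS senses cytosolic DNA, STING relays its signal, CDK1 drives mitosis and ATR is a checkpoint kinase.

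Total counts per library ran from 5590061 in replicate 2 of WT IR 3 d in part 1 to 18585999 in replicate 2 of the DKO with ATRi. No pair of replicates agreed within sampling noise: the chi-square per gene between the 2 libraries of a group ran from 1.55 to 46.9. It was 35.4, 21.6, 33.6 and 46.9 in the 4 WT groups of part 1 and 28.2 in STING KO, and at most 3.38 elsewhere. Nothing in the labels says that the libraries of a group came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. In part 1 this spread was pooled over groups that differ in it, so p-values between WT groups can understate their own spread. Knockout lines were grown from single cells, and the sample names give no clone. Each knockout comparison therefore sets line against line. The effect of a lost gene cannot be told from other differences between the lines.

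The targeted genes were read first. Coordinates printed here and below are the deposited intervals, which can take in neighbouring genes. MB21D1, which encodes cGAS (ENSG00000164430, chromosome 6, 74078278 to 74161999), had 20 and 15 counts in the cGAS KO libraries and 251 and 254 in WT at 5 days, a log2 fold change of -3.67 ± 0.24 (edgeR adjusted p = 3.54e-05). TMEM173, which encodes STING (ENSG00000184584, chromosome 5, 138855119 to 138862520), had 127 and 103 counts in STING KO and 1214 and 894 in WT (-2.83 ± 0.23, edgeR adjusted p = 0.000182). XRCC4 mRNA (ENSG00000152422, chromosome 5, 82348665 to 82649606) was 7.0 ± 0.896 CPM (SD, n = 2) in XRCC4 KO and 8.52 ± 1.56 in WT in part 1, and 8.58 ± 0.314 and 7.10 ± 0.0559 in part 2. Neither difference passed (edgeR adjusted p = 0.379 and 0.13). Small edits need not lower an mRNA, so the XRCC4 level does not check that label.

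Of the p53 target genes, 40 of 40 fell and 0 rose (40 and 0 adjusted over the list alone) in the XRCC4 p53 DKO against XRCC4 KO. In RPE-1, MB21D1 was 342 ± 4.59 CPM in WT cGAS, 0.143 and 6.35 CPM in WT replicates 1 and 2 (2 and 100 counts), and 0.359 ± 0.0788 in p53 KO. TERT, the telomerase gene that the RPE-1 line carries as a transgene (ENSG00000164362, chromosome 5, 1253262 to 1295184), lay between 9.27 and 24.4 CPM in the RPE-1 libraries and at or below 2.24 CPM in MCF10A. CDK1 (ENSG00000170312, chromosome 10, 62538089 to 62554610) and ATR (ENSG00000175054, chromosome 3, 142168077 to 142297668) were inhibited as proteins, so their mRNA checks nothing. CDK1 mRNA was 89.4 ± 63.2 CPM with CDK1i and 26.2 ± 8.35 with DMSO. ATR mRNA was 73.7 ± 1.55 CPM with ATRi and 74.6 ± 1.84 without it in XRCC4 KO.

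**Figure D1:**
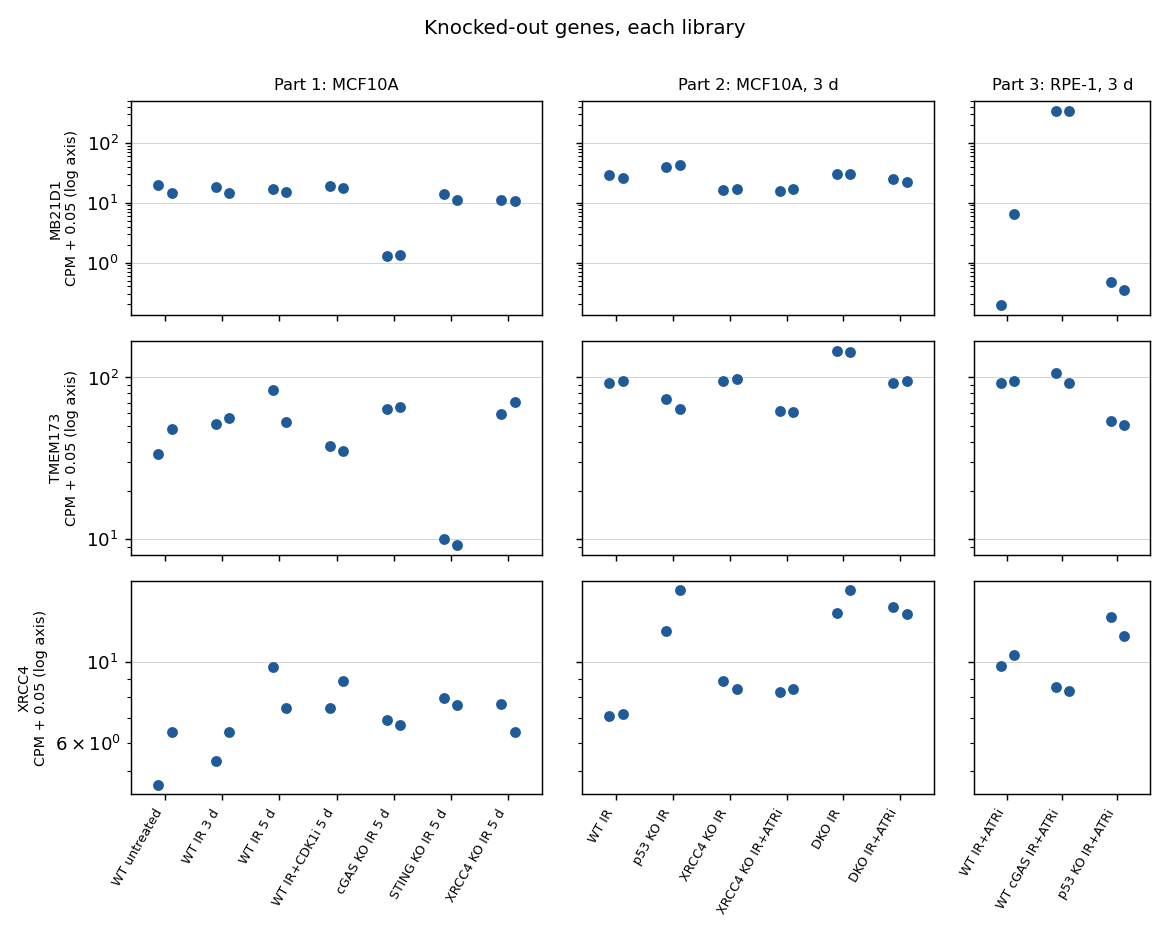
Scaled counts (CPM, log axis, 0.05 added so that 0 can be drawn) of 3 knocked-out genes in each of the 32 libraries, 1 point per library, grouped by part. MB21D1 is low in cGAS KO and in RPE-1 WT and p53 KO, TMEM173 is low in STING KO, and the XRCC4 difference between XRCC4 KO and WT passes in neither part 1 nor part 2.

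The first question of part 1 was how radiation changed MCF10A cells over time. At 3 days CDKN1A, which encodes the cell cycle inhibitor p21 (ENSG00000124762, chromosome 6, 36644237 to 36655116), rose by 2.54 ± 0.20 on the log2 scale, and MDM2, which encodes the p53 ubiquitin ligase, by 1.90 ± 0.16 (edgeR adjusted p = 0.000449 and 0.000449). Of the p53 target genes, 20 of 40 rose and 0 fell (29 and 0 adjusted over the list alone), with ACER2 and TP53INP1 also at 2.87 ± 0.37 and 1.99 ± 0.14 and a median of 0.76 (camera adjusted p = 3.77e-19, adjusted p = 0.0989 with an estimated correlation). Of the interferon-stimulated genes 1 of 57 rose and 0 fell (1 and 0 adjusted over the list alone), at a median log2 fold change of 0.87, or 0.84 with members at 0 counts set to their bound (camera adjusted p = 6.9e-05, adjusted p = 0.714 with an estimated correlation). Without IR 3 d replicate 1 the list no longer passed, at a median of 0.30 (camera adjusted p = 0.242). The gene that rose was ZC3HAV1, an antiviral zinc finger protein (0.86 ± 0.17, edgeR adjusted p = 0.0185). IFIT1, an antiviral effector (ENSG00000185745, chromosome 10, 90973326 to 91174314, an interval it shares with IFIT2), stood at 20.2 ± 17.9 against 0.706 ± 0.140 CPM (SD, n = 2) and did not pass (edgeR adjusted p = 0.0581), though it did with a replicate block (edgeR adjusted p = 0.027) and with DESeq2 (adjusted p = 0.000174).

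Of the NF-kB and secretory (SASP) inflammatory genes, 4 of 35 rose and 0 fell (12 and 4 adjusted over the list alone), among them the collagenase gene MMP1 (3.61 ± 0.74). The median was 0.94 (camera adjusted p = 0.00155, adjusted p = 0.714 with an estimated correlation). Histone genes with polyadenylated transcripts gave 1.45 (camera adjusted p = 0.00155, adjusted p = 0.714 with an estimated correlation), where 2 of 13 rose and 0 fell (9 and 0 adjusted over the list alone). For cholesterol biosynthesis genes the median was 0.40, with 24 of 24 not passing alone (camera adjusted p = 0.00161, adjusted p = 0.714 with an estimated correlation), and the list levels of the libraries overlapped: 6.16 and 6.54 log2 CPM in replicates 1 and 2 at 3 days, and 5.61 and 6.20 untreated, each higher at 3 days than untreated within its replicate number. Luminal epithelial markers did not pass, at 0.32 (but -0.01 on FPKM), where 2 of 15 rose and 0 fell (3 and 0 adjusted over the list alone) (camera adjusted p = 0.0588, and 0.0425 with a replicate block). G2-M genes were at a median of 0.40 while CDC25B, a mitotic phosphatase, fell (-0.90 ± 0.19) (camera adjusted p = 0.00498, adjusted p = 0.714 with an estimated correlation). G2-M levels differed between replicates within the WT groups of part 1: the list mean was 2.79 and 4.48 log2 CPM in untreated replicates 1 and 2, a range that held both libraries of 3 days. Among the genes with the largest changes outside the lists, the phospholipase gene PLA2G2A (-2.62 ± 0.73) and KLF15, a transcription factor (-2.80 ± 0.60), fell, and HEPHL1 rose to 12.6 ± 7.91 CPM from 0.0506 ± 0.0715.

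In all, 555 genes were higher and 436 lower at 3 days, of 15190 tested. With only the libraries of these groups in the fit edgeR called 1 gene, on the deposited FPKM limma called 111 higher and 31 lower, and without WT IR 3 d replicate 1, replicate 2 or untreated replicate 1 the counts were 330, 131 and 528. CDC25B, KLF15, MMP1, PLA2G2A and ZC3HAV1 no longer passed without at least 1 of these libraries (edgeR adjusted p 0.0521 to 0.219). With DESeq2 PLA2G2A did not pass (adjusted p = 0.19).

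At 5 days against untreated cells IFIT1 reached 708 ± 607 CPM from 0.706 ± 0.140 (SD, n = 2), a log2 fold change of 9.92 ± 1.33 (edgeR adjusted p = 0.00139). The ubiquitin-like modifier ISG15 (6.90 ± 0.93), the antiviral GTPase MX1 (6.69 ± 1.08) and the RNA sensors DDX58 (RIG-I, 5.13 ± 0.70) and IFIH1 (MDA5, 3.60 ± 0.62) rose too, with edgeR adjusted p at or below 0.00364. The chemokine gene CCL5 rose to 5.24 ± 4.06 from 0.0732 ± 0.103 CPM. Of the interferon-stimulated genes 56 of 57 rose and 0 fell (56 and 0 adjusted over the list alone). The median was 3.93 (camera adjusted p = 7.81e-24, adjusted p = 0.445 with an estimated correlation). XAF1, a pro-apoptotic interferon target with 0 counts in untreated cells, was at least 213-fold higher. IFNB1, which encodes interferon beta, had 14 and 4 counts at 5 days and 0 and 0 in untreated cells, too few to be tested. Of the interferon and T-cell chemokine genes 4 of 6 rose and 0 fell (4 and 0 adjusted over the list alone). The median was 6.52, or 5.02 with members at 0 counts set to their bound (camera adjusted p = 0.0256, adjusted p = 0.445 with an estimated correlation).

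The 2 libraries differed in size of response: the mean of the interferon-stimulated genes was 7.97 log2 CPM in replicate 1 and 6.46 in replicate 2 at 5 days, against 3.18 ± 0.05 (SD, n = 2) untreated and 4.22 ± 0.77 at 3 days. Of the antigen presentation and interferon gamma genes 21 of 33 rose and 0 fell (25 and 0 adjusted over the list alone), led by the guanylate-binding protein genes GBP4 (4.82 ± 1.12) and GBP5 (4.21 ± 0.43). The median was 1.22 (camera adjusted p = 1.81e-08, adjusted p = 0.445 with an estimated correlation). Of the nucleic acid sensing genes 9 of 18 rose and 0 fell (9 and 0 adjusted over the list alone), including SAMHD1, a dNTPase (3.11 ± 0.43). The median was 0.78 (camera adjusted p = 0.00137, adjusted p = 0.445 with an estimated correlation). Among p53 targets 31 of 40 rose and 0 fell (34 and 0 adjusted over the list alone), with CDKN1A at 3.00 ± 0.21 and a median of 0.85 (camera adjusted p = 1.74e-14, adjusted p = 0.213 with an estimated correlation).

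Of the epidermal differentiation genes 13 of 37 rose and 0 fell (14 and 0 adjusted over the list alone), among them the psoriasin gene S100A7 (8.36 ± 1.13) and the keratin gene KRT4 (6.41 ± 1.94). The median was 2.97, or 2.71 with members at 0 counts set to their bound (camera adjusted p = 7.65e-05, adjusted p = 0.449 with an estimated correlation). Histone genes gave 2.49, where 10 of 13 rose and 0 fell (10 and 0 adjusted over the list alone) (camera adjusted p = 7.65e-05, adjusted p = 0.445 with an estimated correlation). For hypoxia and glycolysis genes 12 of 26 rose and 0 fell (12 and 0 adjusted over the list alone), with the carbonic anhydrase gene CA9 at 2.89 ± 0.84. The median was 0.63 (camera adjusted p = 0.000254, adjusted p = 0.445 with an estimated correlation). Integrated stress and unfolded protein response genes were lower as a list: 9 of 26 fell and 2 rose (13 and 2 adjusted over the list alone), with the amino acid synthesis genes PHGDH and ASNS at -3.40 ± 1.04 and -2.77 ± 0.92. The median was -0.72 (camera adjusted p = 0.00853, adjusted p = 0.445 with an estimated correlation). Of the luminal epithelial markers 7 of 15 rose and 0 fell (8 and 0 adjusted over the list alone), and their median was 1.44 (camera adjusted p = 0.00352, adjusted p = 0.445 with an estimated correlation). In total 2293 genes were higher and 2165 lower. edgeR on only these libraries called 1078, limma on FPKM called 1386 higher and 75 lower, and leaving out WT IR 5 d replicate 1 gave 1641. ASNS, CA9, GBP4, KRT4, PHGDH and XAF1 no longer passed without at least 1 of these libraries (edgeR adjusted p 0.0558 to 0.188). With a replicate block KRT4, PHGDH and ASNS did not pass (edgeR adjusted p = 0.0518, 0.0521 and 0.0719), nor did CA9 with DESeq2 (adjusted p = 0.0586).

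Between 3 and 5 days, OAS3, an oligoadenylate synthetase of the antiviral RNase L pathway (3.58 ± 0.55), the GTPase gene MX2 (5.08 ± 0.84) and LAMP3, a lysosomal membrane protein (4.18 ± 0.71), rose (edgeR adjusted p at or below 0.0481). Among interferon-stimulated genes 11 of 57 rose and 0 fell (57 and 0 adjusted over the list alone). The median was 3.14 (camera adjusted p = 6.55e-52, adjusted p = 0.296 with an estimated correlation). For antigen presentation genes 2 of 33 rose and 0 fell (26 and 0 adjusted over the list alone), with CD74, the invariant chain of MHC class II, at 2.14 ± 0.34, and the median was 1.11 (camera adjusted p = 1.93e-19, adjusted p = 0.296 with an estimated correlation). HMGA1, a chromatin architectural protein gene, fell (-1.66 ± 0.18). edgeR called 33 genes higher and 7 lower, and 150 and 40 with a replicate block. On only these 4 libraries it called 0, with 1967 genes at an unadjusted p under 0.05, while DESeq2 on all of part 1 called 295 higher and 135 lower and limma on FPKM 390 higher and 5 lower. Without IR 3 d replicate 1 or 2, or IR 5 d replicate 1 or 2, edgeR called 0, 0, 0 and 236 genes, with 1626, 1864, 953 and 2285 at an unadjusted p under 0.05. Without IR 5 d replicate 1 the interferon median was 2.08, and CD74, HMGA1, LAMP3, MX2 and OAS3 no longer passed without at least 1 of these libraries (edgeR adjusted p 0.0694 to 0.252). CD74 did not pass with DESeq2 either (adjusted p = 0.103).

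**Figure D2:**
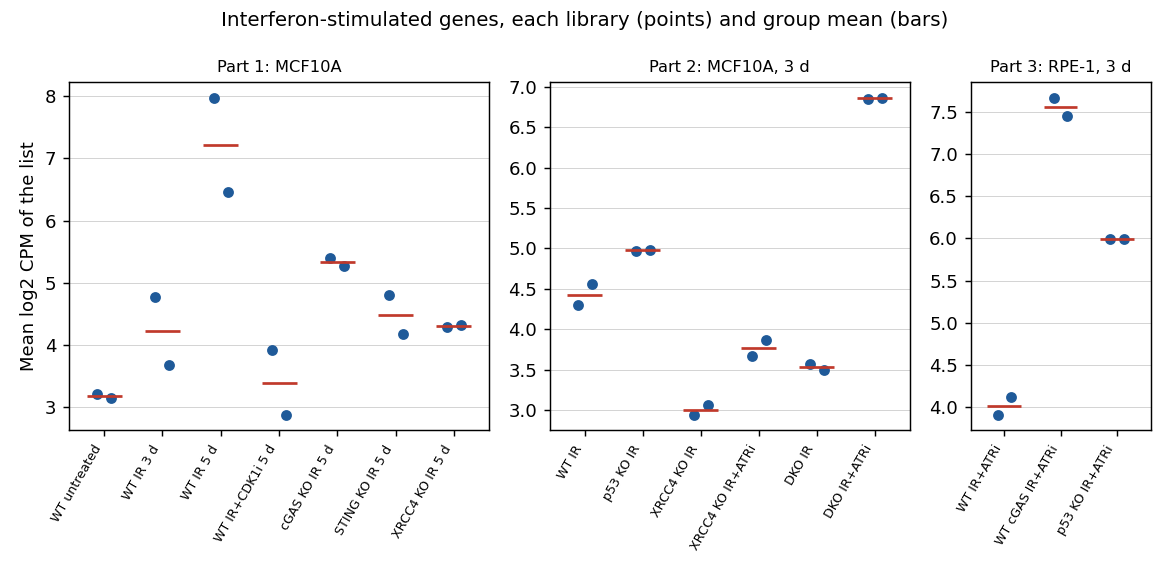
Mean log2 CPM of the interferon-stimulated genes (prior count 2) in each library, by group, in 3 panels for the 3 parts. Points are libraries and bars are group means. Levels cannot be set across panels because each part was scaled separately. In part 1 WT cells at 5 days reach 7.97 and 6.46, and in part 2 the DKO with ATRi reaches 6.85 and 6.86.

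Part 1 next asked whether cell cycle arrest with CDK1i changes the response at 5 days. IFIT1 fell from 708 ± 607 to 11.5 ± 11.3 CPM (SD, n = 2; -5.93 ± 1.01, edgeR adjusted p = 0.00904), and ISG15 (-5.74 ± 0.85), MX1 (-6.93 ± 1.08) and CCL5 (-4.44 ± 0.85) fell with it. In the interferon-stimulated list 57 of 57 fell and 0 rose (57 and 0 adjusted over the list alone). The median was -3.69 (camera adjusted p = 3.99e-33, adjusted p = 0.244 with an estimated correlation). Of the NF-kB and SASP genes 21 of 35 fell and 0 rose (26 and 0 adjusted over the list alone), with the lipocalin gene LCN2 at -4.88 ± 0.96. The median was -1.83 (camera adjusted p = 6.63e-15, adjusted p = 0.153 with an estimated correlation). Of the antigen presentation genes 30 of 33 fell and 0 rose (33 and 0 adjusted over the list alone), with GBP5 at -4.89 ± 0.44. The median was -1.92 (camera adjusted p = 1.34e-20, adjusted p = 0.174 with an estimated correlation). Of the G2-M genes 7 of 45 rose and 0 fell (43 and 0 adjusted over the list alone), with HMMR, a spindle protein, at 2.28 ± 0.43. The median was 1.58 (camera adjusted p = 2.17e-16, adjusted p = 0.343 with an estimated correlation). Of the G1-S and replication genes 10 of 50 rose and 0 fell (40 and 0 adjusted over the list alone). The median was 1.25 (camera adjusted p = 1.51e-16, adjusted p = 0.343 with an estimated correlation). G2-M means were 4.98 and 6.22 log2 CPM in CDK1i replicates 1 and 2.

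Among mesenchymal and extracellular matrix genes 8 of 32 fell and 0 rose (10 and 0 adjusted over the list alone). The median was -1.16 (camera adjusted p = 7.94e-05, adjusted p = 0.423 with an estimated correlation). Histone genes gave -1.40, where 6 of 13 fell and 0 rose (11 and 0 adjusted over the list alone) (camera adjusted p = 7.65e-07, adjusted p = 0.252 with an estimated correlation). Luminal markers gave -0.29, where 2 of 15 fell and 0 rose (3 and 0 adjusted over the list alone), and did not pass (camera adjusted p = 0.0666, and 0.0313 with a replicate block). Against untreated cells, the irradiated CDK1i cells had an interferon-stimulated median of 0.26, where 2 of 57 rose and 4 fell (2 and 3 adjusted over the list alone) (camera adjusted p = 0.389). p53 targets stayed higher than untreated, at 0.76, where 24 of 40 rose and 1 fell (27 and 2 adjusted over the list alone) (camera adjusted p = 1.38e-11, adjusted p = 0.358 with an estimated correlation). CDK1i against DMSO gave 718 genes higher and 1120 lower. edgeR on these 4 libraries alone called 0, with 3484 at an unadjusted p under 0.05, DESeq2 on all of part 1 called 1121 higher and 1081 lower, and limma on FPKM 17 higher and 540 lower. Leaving out DMSO replicate 1 or 2 or CDK1i replicate 2 gave 439, 756 and 424 genes, and CCL5, HMMR, IFIT1 and LCN2 no longer passed without at least 1 of these libraries (edgeR adjusted p 0.0524 to 0.086).

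The next comparison asked how loss of cGAS changes the irradiated state at 5 days. MX1 fell from 222 ± 189 to 3.45 ± 0.104 CPM (SD, n = 2; -6.00 ± 1.01, edgeR adjusted p = 0.00643), IFITM1, an antiviral membrane protein, changed by -5.15 ± 0.73, and the class I gene HLA-B (ENSG00000234745, chromosome 6, 31236526 to 31325414), whose reads can be shared with its paralogs, by -4.26 ± 0.41. IFIT1 was at -2.19 ± 0.84 and did not pass (edgeR adjusted p = 0.119). For interferon-stimulated genes 34 of 57 fell and 0 rose (48 and 0 adjusted over the list alone). The median was -1.86 (camera adjusted p = 6.4e-19, adjusted p = 0.367 with an estimated correlation). Their level was above that of untreated WT cells, which differ from these in both line and radiation. The median against untreated WT cells was 1.88, or 1.66 with members at 0 counts set to their bound, where 35 of 57 rose and 3 fell (39 and 4 adjusted over the list alone) (camera adjusted p = 2.43e-07, adjusted p = 0.869 with an estimated correlation).

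Antigen presentation genes were lower than in irradiated WT cells: 27 of 33 fell and 0 rose (31 and 0 adjusted over the list alone), with CD74 at -4.65 ± 0.44. The median was -1.68 (camera adjusted p = 1.87e-18, adjusted p = 0.356 with an estimated correlation). Of the NF-kB and SASP genes 10 of 35 fell and 0 rose (15 and 0 adjusted over the list alone), with the adhesion molecule gene ICAM1 at -3.74 ± 0.30. The median was -1.15 (camera adjusted p = 4.66e-08, adjusted p = 0.356 with an estimated correlation). Cholesterol biosynthesis genes were higher: 6 of 24 rose and 0 fell (7 and 0 adjusted over the list alone), with DHCR7, a reductase of the pathway, at 1.18 ± 0.28. The median was 0.75 (camera adjusted p = 1.45e-07, adjusted p = 0.367 with an estimated correlation). For p53 targets 1 of 40 rose and 1 fell (0 and 1 adjusted over the list alone), with the stress cytokine gene GDF15 at -2.26 ± 0.45, and the list did not pass (camera adjusted p = 0.927). Luminal markers gave a median of -0.38 (camera adjusted p = 0.0198, adjusted p = 0.613 with an estimated correlation), with the keratin gene KRT8 at -1.44 ± 0.32. The guanine deaminase gene GDA (4.08 ± 0.41) rose, and the glutamate transporter gene SLC1A1, at 0 counts in the KO, was at least 56.5-fold lower. edgeR called 1010 genes higher and 1045 lower, 3124 in all on only these 4 libraries, and limma on FPKM called 51 higher and 498 lower. Leaving out WT replicate 1 or 2, or KO replicate 1 or 2, gave 826, 976, 365 and 480 genes, and without WT replicate 1 the interferon median was -0.87. DHCR7, GDF15, KRT8 and MX1 no longer passed without at least 1 of these libraries (edgeR adjusted p 0.0666 to 0.131).

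In STING KO cells MX1 fell to 0.654 ± 0.296 from 222 ± 189 CPM (SD, n = 2; -8.36 ± 1.24), and IFIT1 (-3.45 ± 0.89), ISG15 (-3.80 ± 0.76) and DDX58 (-2.93 ± 0.62) fell as well (edgeR adjusted p at or below 0.0307). Of the interferon-stimulated genes 50 of 57 fell and 0 rose (55 and 0 adjusted over the list alone). The median was -2.70 (camera adjusted p = 2.2e-26, adjusted p = 0.402 with an estimated correlation). Against untreated WT cells the median was 1.14, where 23 of 57 rose and 3 fell (26 and 3 adjusted over the list alone) (camera adjusted p = 0.00191, adjusted p = 0.951 with an estimated correlation). Among antigen presentation genes 27 of 33 fell and 0 rose (30 and 0 adjusted over the list alone), with GBP4 at -4.66 ± 1.09. The median was -1.67 (camera adjusted p = 1.26e-18, adjusted p = 0.402 with an estimated correlation). Hypoxia and glycolysis genes were lower, at -0.64, where 7 of 26 fell and 0 rose (11 and 0 adjusted over the list alone), with CA9 at -4.95 ± 1.01 (camera adjusted p = 1.26e-05, adjusted p = 0.402 with an estimated correlation). Epidermal genes had a median of 0.72, where 7 of 37 rose and 1 fell (11 and 1 adjusted over the list alone), with the keratin gene KRT1 at 4.21 ± 1.09 (camera adjusted p = 0.0157, adjusted p = 0.714 with an estimated correlation). Their list levels overlapped between the groups: 4.38 and 5.93 log2 CPM in STING KO replicates 1 and 2, and 4.93 and 3.87 in WT.

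For luminal markers in STING KO 3 of 15 fell and 0 rose (5 and 0 adjusted over the list alone), at a median of -0.98 (camera adjusted p = 0.0142, adjusted p = 0.617 with an estimated correlation). PYCARD, an inflammasome adaptor gene, had 0 counts in STING KO and was at least 49.2-fold lower than in WT. Set directly against each other, the cGAS and STING KO groups gave an interferon-stimulated median of 0.81, higher in cGAS KO (camera adjusted p = 1.3e-14, adjusted p = 0.966 with an estimated correlation). Of all 15190 genes tested, edgeR called 14 higher and 14 lower in cGAS KO than in STING KO. The STING KO replicates differed by a chi-square per gene of 28.2, and edgeR recovered 48 of 100 simulated 2-fold changes in part 1. A low count therefore does not show that the groups are alike. In STING KO against WT, edgeR called 1129 genes higher and 1174 lower, 806 in all on only these 4 libraries, and limma on FPKM 41 higher and 717 lower. Leaving out WT replicate 1 or 2, or KO replicate 1 or 2, gave 1048, 1130, 1109 and 1150 genes, with an interferon median of -1.73 in the first case. CA9, DDX58, GBP4, IFIT1, ISG15 and KRT1 no longer passed without at least 1 of these libraries (edgeR adjusted p 0.0547 to 0.252).

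XRCC4 KO cells at 5 days had fewer transcripts of both interferon-stimulated and mitotic genes than WT cells. IFIT1 (-4.15 ± 0.92), MX1 (-8.75 ± 1.29) and HLA-B (-4.20 ± 0.41) fell (edgeR adjusted p at or below 0.0115), and the proliferation marker MKI67 fell to 9.74 ± 0.408 from 88.6 ± 28.7 CPM (SD, n = 2; -3.19 ± 0.61, edgeR adjusted p = 0.00631). Among interferon-stimulated genes 51 of 57 fell and 0 rose (55 and 0 adjusted over the list alone). The median was -2.91 (camera adjusted p = 3.65e-21, adjusted p = 0.436 with an estimated correlation). Against untreated WT cells it was 1.15, where 26 of 57 rose and 4 fell (26 and 4 adjusted over the list alone) (camera adjusted p = 0.00835, adjusted p = 0.904 with an estimated correlation). Among G2-M genes 30 of 45 fell and 0 rose (40 and 0 adjusted over the list alone), with the mitotic phosphatase gene CDC25C at -3.71 ± 0.79. The median was -2.46 (camera adjusted p = 5.33e-09, adjusted p = 0.436 with an estimated correlation). Of the G1-S genes 11 of 50 fell and 1 rose (14 and 1 adjusted over the list alone), with the thymidine kinase gene TK1 at -2.86 ± 0.90. The median was -1.13 (camera adjusted p = 4.23e-05, adjusted p = 0.585 with an estimated correlation). CDKN1A rose (0.81 ± 0.19), and p53 targets gave 0.25 (but -0.27 on FPKM), where 7 of 40 rose and 2 fell (7 and 2 adjusted over the list alone) (camera adjusted p = 0.00801, adjusted p = 0.436 with an estimated correlation). NF-kB and SASP genes were lower, at -1.98, or -1.95 with members at 0 counts set to their bound, where 19 of 35 fell and 0 rose (22 and 0 adjusted over the list alone), with the cytokine gene CSF3 at -6.22 ± 0.71 (camera adjusted p = 1.78e-09, adjusted p = 0.436 with an estimated correlation). Luminal markers did not pass, at -0.61, where 5 of 15 fell and 0 rose (6 and 0 adjusted over the list alone) (camera adjusted p = 0.0541, and 0.0261 with a replicate block).

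edgeR called 1882 genes higher and 1876 lower, and limma on FPKM 67 higher and 1658 lower. Leaving out WT replicate 1 or 2, or KO replicate 1 or 2, gave 2222, 1951, 1440 and 1415 genes, with an interferon median of -1.93 in the first case. CDC25C, CDKN1A, IFIT1, MKI67 and TK1 no longer passed without at least 1 of these libraries (edgeR adjusted p 0.0507 to 0.179). The 3 knockouts and CDK1i were each set against the same 2 WT libraries, which were not split between the comparisons, so their calls overlap in part by construction. cGAS KO and STING KO shared 806 genes higher and 755 lower, where 75.1 and 80.8 would be expected for independent lists. The covariance of their log2 fold changes across genes was 0.722, against 0.108 in 20 simulations in which the groups differed from the control by chance alone, and the correlation was 0.804 against 0.487. CDK1i and cGAS KO shared 131 higher and 362 lower (47.7 and 77 expected), with a covariance of 0.353 against 0.107 simulated. Their correlation, 0.413, was below the 0.493 simulated. The simulations draw all libraries independently and leave out the correlation of same-numbered WT libraries (0.439 between CDK1i and DMSO at 5 days), so they are no exact reference for CDK1i. They also leave out shifts that many genes share within a group, so the simulated values are no upper bound for any pair.

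**Figure D3:**
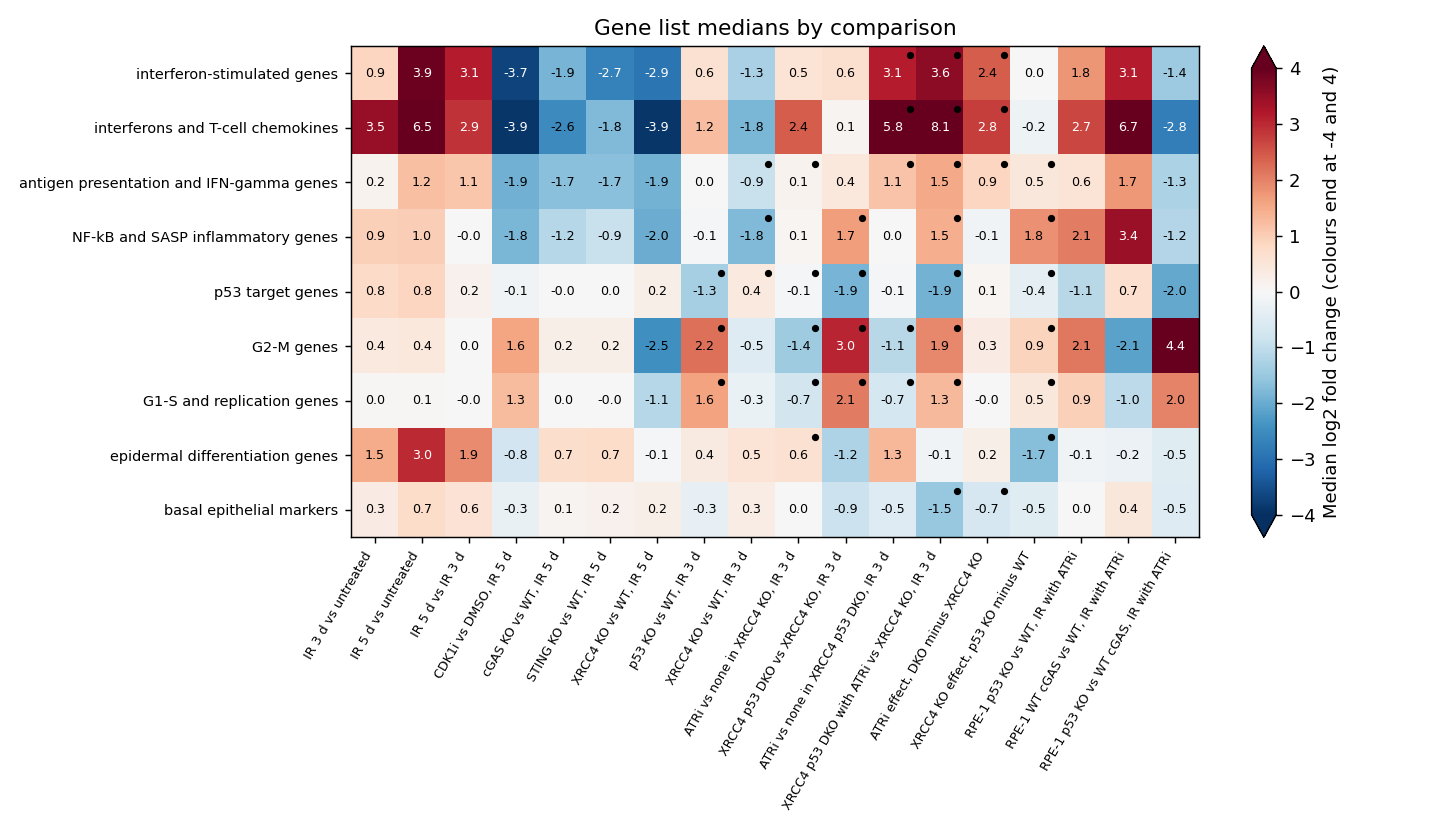
Median log2 fold change (colour and printed value) of the tested members of 9 gene lists (vertical axis) in the 18 comparisons with gene calls (horizontal axis). A dot marks lists called by camera at both the preset and the estimated inter-gene correlation. Interferon-stimulated genes have a median of 3.93 at 5 days after irradiation in WT cells and 3.13 for ATRi in the DKO.

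Part 2 asked how p53 loss acts in cells with and without XRCC4, and how checkpoint inhibition acts in cells without XRCC4. Without p53, the cell cycle inhibitor gene CDKN1A fell from 1356 ± 40.6 to 141 ± 6.17 CPM (SD, n = 2; -3.27 ± 0.04), and MDM2 (-2.42 ± 0.05) and GDF15 (-3.97 ± 0.07) fell too (edgeR adjusted p at or below 2.56e-23). Of the p53 targets 39 of 40 fell and 0 rose (39 and 0 adjusted over the list alone). The median was -1.34 (camera adjusted p = 5.07e-27). Proliferation genes rose: of the G2-M genes 45 of 45 rose and 0 fell (45 and 0 adjusted over the list alone), with MKI67 at 2.43 ± 0.05, at 2.19 (camera adjusted p = 2.6e-41), and of the G1-S genes 50 of 50 rose and 0 fell (50 and 0 adjusted over the list alone), with the transcription factor gene E2F2 at 2.59 ± 0.12. The median was 1.62 (camera adjusted p = 2.07e-33). Interferon-stimulated genes were modestly higher: 42 of 58 rose and 9 fell (42 and 9 adjusted over the list alone), with IFIT1 at 1.77 ± 0.24, OASL, an antiviral OAS-like protein gene, at 1.69 ± 0.11 and the restriction factor gene TRIM22 at -2.81 ± 0.06. The median was 0.62 (camera adjusted p = 9.68e-06, adjusted p = 0.373 with an estimated correlation).

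Cholesterol genes were lower in p53 KO, at -0.29, where 16 of 24 fell and 1 rose (16 and 1 adjusted over the list alone) (camera adjusted p = 0.000361). Basal markers gave -0.33, where 13 of 18 fell and 5 rose (13 and 5 adjusted over the list alone), although the basal keratin gene KRT14 rose (3.60 ± 0.05) (camera adjusted p = 0.00323, adjusted p = 0.283 with an estimated correlation). The toll-like receptor gene TLR2 rose as well (4.76 ± 0.24). edgeR called 4306 genes higher and 4490 lower, of 16632 tested, and limma on FPKM 2805 higher and 1666 lower.

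XRCC4 KO against WT at 3 days gave lower interferon-stimulated and inflammatory genes. IFIT1 fell from 16.2 ± 4.77 to 2.63 ± 0.652 CPM (SD, n = 2; -2.65 ± 0.47), with MX1 at -3.15 ± 0.35 and the cytokine genes IL1B and CXCL8 at -2.96 ± 0.05 and -3.60 ± 0.06 (edgeR adjusted p at or below 0.0028). In the interferon-stimulated list 51 of 58 fell and 2 rose (51 and 2 adjusted over the list alone). The median was -1.31 (camera adjusted p = 2.78e-13, adjusted p = 0.119 with an estimated correlation). Among NF-kB and SASP genes 27 of 37 fell and 4 rose (27 and 5 adjusted over the list alone), with LCN2 at -4.21 ± 0.09. The median was -1.75, or -1.49 with members at 0 counts set to their bound (camera adjusted p = 6.39e-11). Of the antigen presentation genes 30 of 35 fell and 1 rose (30 and 2 adjusted over the list alone). The median was -0.89, or -0.88 with members at 0 counts set to their bound (camera adjusted p = 7.42e-11). p53 targets were higher, at 0.39, where 33 of 40 rose and 1 fell (34 and 1 adjusted over the list alone), with TP53INP1 at 1.17 ± 0.06 (camera adjusted p = 2.86e-09). Luminal markers were lower, at -0.96, where 11 of 15 fell and 2 rose (11 and 2 adjusted over the list alone) (camera adjusted p = 5.22e-05, adjusted p = 0.0562 with an estimated correlation), and KRT14 rose (6.81 ± 0.05). PYCARD, at 0 counts in the KO, was at least 123-fold lower, and the calcium-binding protein gene CALB1 rose (9.56 ± 0.21). edgeR called 4749 genes higher and 4581 lower, and limma on FPKM 2036 higher and 3701 lower.

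ATRi in XRCC4 KO cells raised some interferon-stimulated genes and lowered cell cycle genes. IFIT1 rose from 2.63 ± 0.652 to 16.5 ± 5.63 CPM (SD, n = 2; 2.65 ± 0.47), IFI6, an interferon-induced mitochondrial protein gene, by 2.87 ± 0.25, and MKI67 fell (-1.48 ± 0.07) (edgeR adjusted p at or below 0.0111). MX1 was at 0.83 ± 0.52 and did not pass. For interferon-stimulated genes 30 of 58 rose and 1 fell (36 and 1 adjusted over the list alone). The median was 0.54, or 0.52 with members at 0 counts set to their bound (camera adjusted p = 8.07e-16, adjusted p = 0.114 with an estimated correlation). In the G2-M list 44 of 45 fell and 0 rose (44 and 0 adjusted over the list alone), at -1.43 (camera adjusted p = 1.62e-51), and of the G1-S genes 43 of 50 fell and 0 rose (46 and 0 adjusted over the list alone). The median was -0.74 (camera adjusted p = 1.79e-31). Histone genes were higher, at 0.81, where 11 of 16 rose and 0 fell (12 and 0 adjusted over the list alone) (camera adjusted p = 1.22e-11). CYP1A1, a target of the aryl hydrocarbon receptor, rose (3.64 ± 0.21). edgeR called 1110 genes higher and 1721 lower, DESeq2 473 and 1178, and limma on FPKM 424 higher and 358 lower. Without replicate 1 or 2 of XRCC4 KO, edgeR called 1713 and 1825, and IFIT1 did not pass (edgeR adjusted p = 0.0811 and 0.0542).

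In the DKO, proliferation and NF-kB genes were higher than in XRCC4 KO cells. CDKN1A fell (-3.37 ± 0.04), GDF15 fell (-6.87 ± 0.14), and MKI67 rose from 56.3 ± 0.549 to 599 ± 9.40 CPM (SD, n = 2; 3.41 ± 0.05) (edgeR adjusted p at or below 1.78e-23). The p53 target median was -1.86 (camera adjusted p = 1.88e-24). Of the G2-M genes 45 of 45 rose and 0 fell (45 and 0 adjusted over the list alone). The median was 3.05 (camera adjusted p = 3.05e-34). In the NF-kB and SASP list 28 of 37 rose and 5 fell (29 and 5 adjusted over the list alone), with IL6 at 3.35 ± 0.33 and the cytokine gene IL24 at 6.03 ± 0.12. The median was 1.68 (camera adjusted p = 5.54e-07). Of the interferon-stimulated genes 32 of 58 rose and 9 fell (32 and 9 adjusted over the list alone), with IFIT1 at 1.52 ± 0.55 and TRIM22 at -5.57 ± 0.08. The median was 0.65, or 0.63 with members at 0 counts set to their bound (camera adjusted p = 0.0137, adjusted p = 0.571 with an estimated correlation). Epidermal genes were lower, at -1.24, or -1.37 with members at 0 counts set to their bound, where 22 of 35 fell and 5 rose (22 and 5 adjusted over the list alone), with the kallikrein gene KLK5 at -6.00 ± 0.21 (camera adjusted p = 0.000572, adjusted p = 0.121 with an estimated correlation). edgeR called 5357 genes higher and 5432 lower, and limma on FPKM 6429 higher and 2182 lower. IFIT1 did not pass when any 1 of these 4 libraries was left out (edgeR adjusted p 0.1 to 0.187). Set against p53 KO, the DKO had an interferon-stimulated median of -1.24, or -1.22 with members at 0 counts set to their bound, where 52 of 58 fell and 3 rose (52 and 3 adjusted over the list alone) (camera adjusted p = 2.24e-20, adjusted p = 0.0551 with an estimated correlation).

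ATRi in the DKO raised nearly the whole interferon-stimulated list. IFIT1 rose from 7.50 ± 0.322 to 577 ± 7.28 CPM (SD, n = 2; 6.26 ± 0.22), ISG15 by 4.74 ± 0.09, CCL5 by 4.22 ± 0.20 and DDX58 by 3.79 ± 0.09 (edgeR adjusted p at or below 3.95e-07). IFNB1 had 27 and 56 counts with ATRi and 0 and 1 without, and the interferon lambda gene IFNL2, at 0 counts without ATRi, was at least 26.1-fold higher. Among interferon-stimulated genes 57 of 58 rose and 0 fell (57 and 0 adjusted over the list alone). The median was 3.13 (camera adjusted p = 6.45e-46). Of the interferon and chemokine genes 8 of 9 rose and 0 fell (8 and 1 adjusted over the list alone). The median was 5.81, or 4.70 with members at 0 counts set to their bound (camera adjusted p = 1.77e-05). Among antigen presentation genes 30 of 35 rose and 0 fell (32 and 0 adjusted over the list alone), with GBP1 at 3.44 ± 0.09. The median was 1.13, or 1.11 with members at 0 counts set to their bound (camera adjusted p = 1e-17). Stress response genes were higher, at 0.60, where 20 of 26 rose and 3 fell (20 and 3 adjusted over the list alone), with the transcription factor gene ATF3 at 3.82 ± 0.07 (camera adjusted p = 1.66e-09). Among G2-M genes 45 of 45 fell and 0 rose (45 and 0 adjusted over the list alone). The median was -1.11 (camera adjusted p = 9.24e-29). edgeR called 4342 genes higher and 5387 lower, and limma on FPKM 4152 higher and 1352 lower.

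The ATRi effect on interferon-stimulated genes was larger in the DKO than in XRCC4 KO by a test of the difference itself. The difference was 3.61 ± 0.77 for IFIT1, 3.46 ± 0.22 for ISG15, 3.11 ± 0.20 for DDX58 and 5.01 ± 0.10 for TRIM22 (edgeR adjusted p at or below 0.0119). Without ATRi, TRIM22 was at -5.57 in the DKO against XRCC4 KO, so its difference starts from a lower level in the DKO. In the interferon-stimulated list the effect was higher in 52 of 58 and lower in 0 (54 and 0 adjusted over the list alone), at a median difference of 2.43 (camera adjusted p = 4.6e-51). Of the antigen presentation genes the effect was higher in 23 of 35 and lower in 0 (24 and 0 adjusted over the list alone). The median was 0.87 (camera adjusted p = 4.41e-16). Basal markers differed the other way, at -0.67, where the effect was higher in 1 of 18 and lower in 15 (1 and 15 adjusted over the list alone), with the basal transcription factor gene TP63 at -1.46 ± 0.09 (camera adjusted p = 8.61e-11). In all 2168 genes had a higher and 3494 a lower effect in the DKO, DESeq2 gave 1361 and 2329, and limma on FPKM 839 higher and 290 lower. Without XRCC4 KO replicate 2 the difference for IFIT1 did not pass (edgeR adjusted p = 0.0944).

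With p53 loss and ATRi together against XRCC4 KO alone, IFIT1 rose by 7.78 ± 0.26, ISG15 by 5.39 ± 0.10 and IL6 by 4.72 ± 0.26 (edgeR adjusted p at or below 1.97e-07). For interferon-stimulated genes 57 of 58 rose and 1 fell (57 and 1 adjusted over the list alone). The median was 3.57 (camera adjusted p = 1.84e-25). Of the NF-kB and SASP genes 31 of 37 rose and 5 fell (31 and 5 adjusted over the list alone). The median was 1.46 (camera adjusted p = 4.43e-08). Basal markers were lower, at -1.53, where 17 of 18 fell and 0 rose (17 and 0 adjusted over the list alone) (camera adjusted p = 7.9e-12). Against irradiated WT cells the same group had an interferon-stimulated median of 2.15, where 54 of 58 rose and 3 fell (54 and 3 adjusted over the list alone) (camera adjusted p = 5.66e-23). edgeR called 6180 genes higher and 6152 lower against XRCC4 KO, and limma on FPKM 10859 higher and 2221 lower.

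The effect of XRCC4 loss, taken as the difference between lines, was also compared between p53 KO and p53 WT cells. It was higher in the absence of p53 for IL1B (4.13 ± 0.06), IL6 (3.04 ± 0.43) and CXCL8 (2.93 ± 0.08) (edgeR adjusted p at or below 2.24e-06), while IFIT1 was at -0.25 ± 0.66 and did not pass. Among NF-kB and SASP genes the effect was higher in 28 of 37 and lower in 3 (30 and 3 adjusted over the list alone). The median was 1.84 (camera adjusted p = 4.91e-14). In the G2-M list the effect was higher in 42 of 45 and lower in 0 (43 and 0 adjusted over the list alone). The median was 0.89 (camera adjusted p = 2.68e-21). The interferon-stimulated list did not pass, at 0.01, where the effect was higher in 12 of 58 and lower in 12 (12 and 12 adjusted over the list alone) (camera adjusted p = 0.99). Epidermal genes differed the other way, at -1.69, where the effect was higher in 5 of 35 and lower in 22 (5 and 23 adjusted over the list alone) (camera adjusted p = 2.06e-06). In all 3473 genes had a higher and 3792 a lower effect without p53, and limma on FPKM gave 2288 higher and 861 lower.

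**Figure D4:**
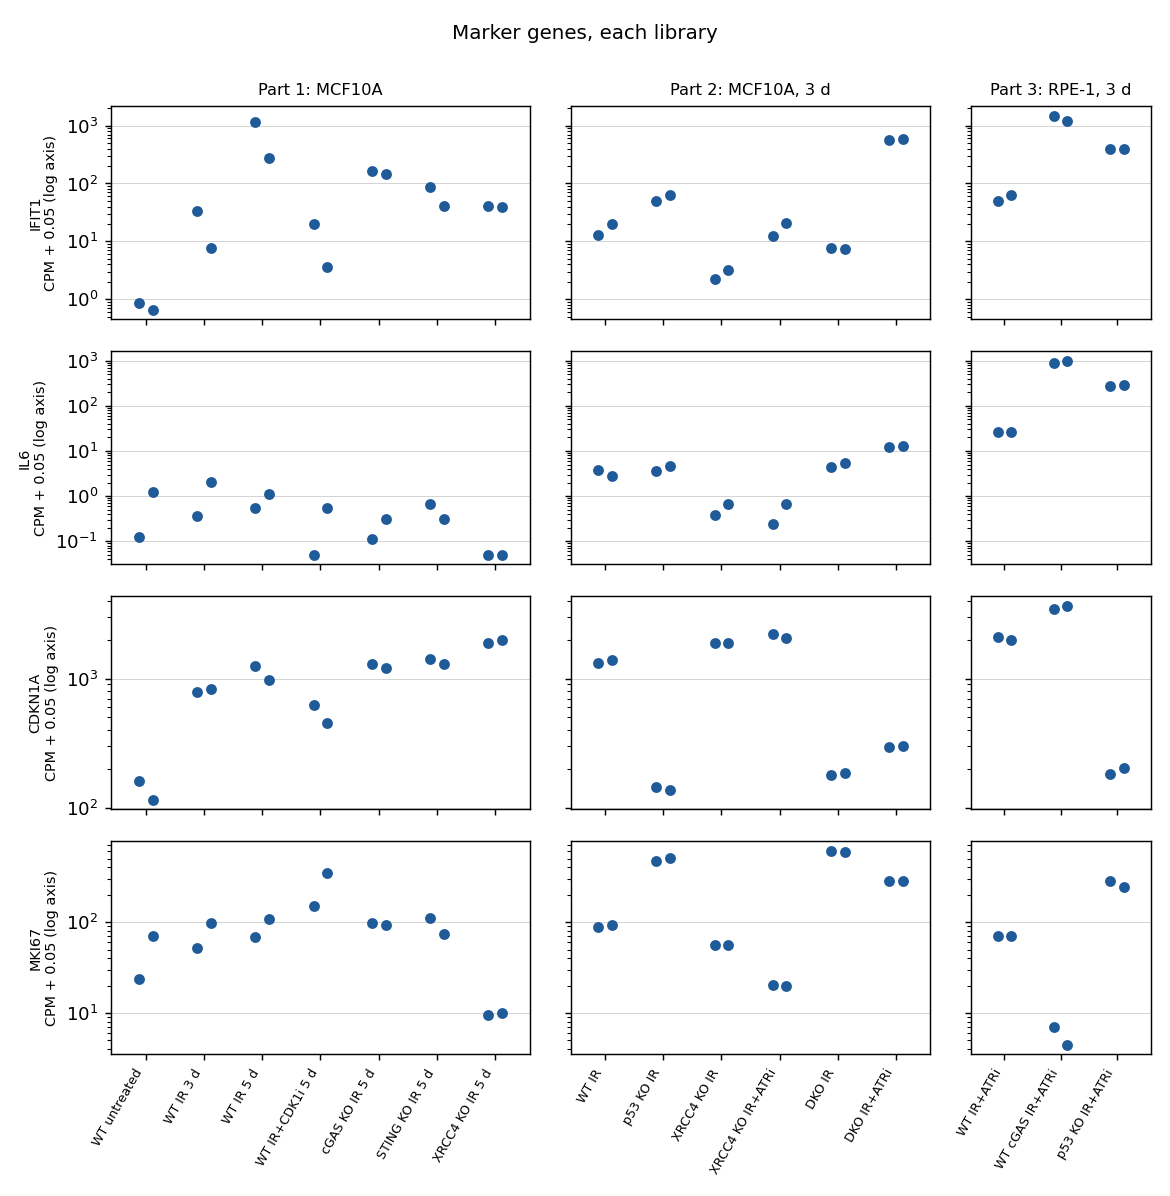
Scaled counts (CPM, log axis, 0.05 added so that 0 can be drawn) of IFIT1, IL6, CDKN1A and MKI67 in each of the 32 libraries, 1 point per library, grouped by part. In the DKO with ATRi IFIT1 averages 577 ± 7.28 CPM (SD, n = 2), and CDKN1A is lower in both p53 KO groups than in their WT groups.

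Part 3 asked about cGAS-independent signalling in RPE-1 cells, all irradiated and given ATRi. In p53 KO against WT, IFIT1 rose from 55.8 ± 9.01 to 398 ± 3.38 CPM (SD, n = 2; 2.83 ± 0.16), MX1 by 4.50 ± 0.62, OAS2 by 4.94 ± 0.20 and IL6 by 3.43 ± 0.07 (edgeR adjusted p at or below 0.00147). IFNB1, at 0 counts in WT, was at least 5.30-fold higher, with 6 and 15 counts. Of the interferon-stimulated genes 53 of 56 rose and 1 fell (53 and 1 adjusted over the list alone). The median was 1.77, or 1.75 with members at 0 counts set to their bound (camera adjusted p = 1.06e-18, adjusted p = 0.271 with an estimated correlation). In the NF-kB and SASP list 30 of 35 rose and 3 fell (30 and 3 adjusted over the list alone), with the chemokine gene CXCL1 at 3.80 ± 0.24 and CCL2 at -4.17 ± 0.09. The median was 2.06 (camera adjusted p = 1.39e-09, adjusted p = 0.271 with an estimated correlation). Of the p53 targets 32 of 38 fell and 3 rose (32 and 3 adjusted over the list alone), with CDKN1A at -3.41 ± 0.05. The median was -1.10 (camera adjusted p = 7.44e-13, adjusted p = 0.271 with an estimated correlation). Of the G2-M genes 45 of 45 rose and 0 fell (45 and 0 adjusted over the list alone), with the transcription factor gene FOXM1 at 3.62 ± 0.06. The median was 2.10 (camera adjusted p = 3.51e-22, adjusted p = 0.271 with an estimated correlation). Mesenchymal genes were lower, at -0.96, where 22 of 35 fell and 6 rose (22 and 6 adjusted over the list alone), with the smooth muscle actin gene ACTA2 at -4.41 ± 0.10 (camera adjusted p = 3.1e-06, adjusted p = 0.271 with an estimated correlation). Immune and blood cell markers were higher, at 1.28, where 4 of 6 rose and 0 fell (4 and 0 adjusted over the list alone), with the monocyte marker CD14 at 3.66 ± 0.40 (camera adjusted p = 0.0487, adjusted p = 0.271 with an estimated correlation, and 0.0536 with a replicate block). edgeR called 5287 genes higher and 5030 lower, of 15469 tested, and limma on FPKM 10034 higher and 2017 lower.

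WT cGAS cells against WT cells showed larger inflammatory values and fewer cell cycle transcripts. MX1 rose from 0.365 ± 0.112 to 67.2 ± 13.7 CPM (SD, n = 2; 7.48 ± 0.38), CCL5 by 8.64 ± 0.18 and CXCL10, a T-cell chemokine gene, by 7.27 ± 0.40 (edgeR adjusted p at or below 2.05e-05). IFNB1 was at least 14-fold higher, with 27 and 24 counts. Among interferon-stimulated genes 56 of 56 rose and 0 fell (56 and 0 adjusted over the list alone). The median was 3.13, or 2.98 with members at 0 counts set to their bound (camera adjusted p = 2.31e-34, adjusted p = 0.23 with an estimated correlation). Of the NF-kB and SASP genes 34 of 35 rose and 0 fell (34 and 0 adjusted over the list alone), with IL6 at 5.16 ± 0.07. The median was 3.44 (camera adjusted p = 1.21e-19, adjusted p = 0.23 with an estimated correlation). Of the nucleic acid sensing genes 13 of 17 rose and 2 fell (13 and 2 adjusted over the list alone). The median was 0.99 (camera adjusted p = 1.33e-05, adjusted p = 0.232 with an estimated correlation). Among G2-M genes 44 of 45 fell and 1 rose (44 and 1 adjusted over the list alone), with MKI67 at -3.61 ± 0.19. The median was -2.13 (camera adjusted p = 1.17e-12, adjusted p = 0.308 with an estimated correlation). p53 targets were higher, at 0.68, where 28 of 38 rose and 6 fell (28 and 6 adjusted over the list alone) (camera adjusted p = 5.21e-07, adjusted p = 0.23 with an estimated correlation). edgeR called 4607 genes higher and 4647 lower, and limma on FPKM 7562 higher and 2170 lower.

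Set directly against WT cGAS, p53 KO cells had lower interferon-stimulated genes: OASL fell by 3.61 ± 0.25, CCL5 was at -5.70 ± 0.11 and IFIT1 at -1.76 ± 0.14 (edgeR adjusted p at or below 0.000853). Of the list 55 of 56 fell and 0 rose (55 and 0 adjusted over the list alone). The median was -1.45 (camera adjusted p = 6.61e-24, adjusted p = 0.24 with an estimated correlation). In the G2-M list 44 of 45 rose and 1 fell (44 and 1 adjusted over the list alone), with MKI67 at 5.50 ± 0.16. The median was 4.44 (camera adjusted p = 1.65e-23, adjusted p = 0.24 with an estimated correlation). edgeR called 4925 genes higher and 5080 lower, and limma on FPKM 5825 higher and 3501 lower.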

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

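The tests of depth and inhibitor action below, and the requirement that a list be called by camera with both the preset and the estimated correlation, were chosen only after the results were seen. The test of scaling was added after the data were seen, with its prediction written before its own result.

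Genes and lists are given here whose change differed between groups by a test of the difference itself. The ATRi effect differed between the DKO and XRCC4 KO in 5662 genes by edgeR (quasi-likelihood). Its median difference was 2.43 for interferon-stimulated genes, 2.75 for interferons and T-cell chemokines, 0.87 for antigen presentation genes, 0.59 for luminal markers, 0.36 for stress response genes and -0.67 for basal markers. The effect of XRCC4 loss, taken as the difference between lines, differed between p53 KO and p53 WT cells in 7265 genes. Its median difference was 1.84 for NF-kB and SASP genes, 0.89 for G2-M genes, 0.47 for G1-S genes, 0.45 for antigen presentation genes, 0.44 for mesenchymal genes, -0.39 for p53 targets and -1.69 for epidermal genes. No group holds more than 2 libraries, so single libraries were not tested against their group.

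The larger interferon-stimulated response to ATRi in the DKO was weighed against 3 technical explanations. A difference in depth would need totals that differ in the same way, but the same difference taken on mean log2 total counts was -0.0493, against 2.43 for the list. With library totals as the only scaling the list's difference was 2.61, so TMM factors do not make it. Less inhibitor action in XRCC4 KO would be expected to shrink effects there. ATRi moved G2-M genes in XRCC4 KO by 1.29 times as much as in the DKO, and interferon-stimulated genes by 0.174 times as much. The 2 lines also differed in p53 and in G2-M levels without ATRi. The G2-M share therefore does not measure inhibitor action alone and cannot decide on it. The values argue against depth and scaling only. A dependence of the interferon response to ATRi on p53 may be put forward as a hypothesis only, since other differences between the DKO and XRCC4 KO lines were not tested. Restoring p53 in the DKO, or giving ATRi to further independent XRCC4 KO clones with and without p53, would test it.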

How the results depend on the processing

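The direction of each list's median under other scalings, and the thinning of counts, were added only after the data were seen. All other alternatives here were planned.

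Counts of genes called by edgeR (quasi-likelihood) at an adjusted p below 0.05 stayed within 1.5 times the reported value in 18 of 18 comparisons with RLE size factors and with a filter of 1 CPM in 2 libraries, and in 17, 17 and 15 of 18 with no filter, with a replicate block and with DESeq2. For 5 against 3 days the count of 40 became 106 with no filter, 190 with a replicate block and 430 with DESeq2. DESeq2 also gave 1651 genes for ATRi in XRCC4 KO and 3690 for the difference of the ATRi effect. The cause was not tested. With only the libraries compared, which leaves fewer libraries to estimate the spread, the counts were 1 for 3 days against untreated, 1078 for 5 days, 0 for 5 against 3 days, 0 for CDK1i, 3124 for cGAS KO and 806 for STING KO, and within 1.5 times elsewhere. At an unadjusted p under 0.05 the zero counts had 1967 and 3484 genes. Counts fell between WT groups and for STING KO, and rose for cGAS KO (2055 to 3124) and XRCC4 KO at 5 days (3758 to 4879). The chi-square per gene between replicates was 21.6 to 46.9 in the WT groups of part 1, 28.2 in STING KO, 2.96 in cGAS KO and 3.38 in XRCC4 KO. The main fit uses a shared spread per gene for all groups of a part. Its p-values between WT groups of part 1 can therefore understate the spread of their own libraries.

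A minimum absolute log2 fold change of 1, which by construction calls fewer genes, left the count for 5 against 3 days within 1.5 times. In part 1 it gave 359 genes for 3 days, 1776 for 5 days, 820 for CDK1i, 753 for cGAS KO, 872 for STING KO and 1584 for XRCC4 KO. In part 2 it gave 1777 for p53 KO, 2608 for XRCC4 KO, 435 for ATRi in XRCC4 KO, 3755 for the DKO against XRCC4 KO, 1963 for ATRi in the DKO, 4990 for the DKO with ATRi, 864 for the difference of the ATRi effect and 2132 for that of the XRCC4 effect. In RPE-1 it gave 2950 for p53 KO, 2494 for WT cGAS and 2749 for p53 KO against WT cGAS.

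On FPKM with a pseudocount of 1 or 0.1, limma called 142 and 196 genes for 3 days, 1461 and 1223 for 5 days, 395 and 303 for 5 against 3 days, 557 and 422 for CDK1i, 549 and 354 for cGAS KO, 758 and 538 for STING KO and 1725 and 1392 for XRCC4 KO in part 1. In part 2 it called 4471 and 4264 for p53 KO, 5737 and 5757 for XRCC4 KO, 782 and 947 for ATRi in XRCC4 KO, 5504 and 4410 for ATRi in the DKO, 1129 and 1023 for the difference of the ATRi effect and 3149 and 3070 for that of the XRCC4 effect. The other 5 counts stayed within 1.5 times. The cause was not tested.

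Leaving out 1 library in turn, with the remaining library assumed to vary like the others, kept 55 of 80 counts within 1.5 times. Lowest and highest counts were 131 to 882 for 3 days, 1641 to 3719 for 5 days, 0 to 236 for 5 against 3 days, 424 to 2337 for CDK1i, 365 to 976 for cGAS KO, 1048 to 1150 for STING KO, 1415 to 2222 for XRCC4 KO at 5 days and 1713 to 2309 for ATRi in XRCC4 KO.

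No called list or named gene turned its direction under an alternative run for it, apart from the list medians under other scalings given below. The interferon-stimulated list kept its side of the threshold in 18 of 18 comparisons with a replicate block, RLE, no filter, only the libraries compared and FPKM with a pseudocount of 1, and in 79 of 80 fits without 1 library. At 3 days against untreated, these gave medians from 0.30 to 1.23 (camera adjusted p 4.58e-09 to 0.242). With an estimated correlation 14 of 17 calls of this list were lost with unchanged medians: 0.87 for 3 days, 3.93 for 5 days, 3.14 for 5 against 3 days, -3.69, -1.86, -2.70 and -2.91 for CDK1i, cGAS KO, STING KO and XRCC4 KO, 0.62, -1.31, 0.54 and 0.65 for p53 KO, XRCC4 KO, ATRi in XRCC4 KO and the DKO, and 1.77, 3.13 and -1.45 in RPE-1. Of 407 results of other lists, 175 lost their call with an estimated correlation and 1 with a replicate block, which added 10.

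Of 142 results of named genes, 31 lost their call with only the libraries compared, 20 with no filter, 16 and 22 on FPKM, 3 of 141 with DESeq2, 3 with a replicate block and 3 with the fold minimum, and 101 of 604 fits without 1 library lost a call. IFIT1 at 3 days gained a call with a replicate block and with DESeq2 (adjusted p = 0.027 and 0.000174). Of 306 list medians, 2 changed sign with RLE, 3 with DESeq2 and 32 on FPKM with either pseudocount. Thinning to the lowest total of a part, added after the data were seen, gave 1.51 in place of 1.51 for the interferon-stimulated difference between the WT libraries of 5 days. For the ATRi difference it gave 2.39 in place of 2.43. The libraries compared have similar totals, so thinning could move little and decides nothing about depth. Replicate numbers pair no samples in the labels. Deviations of same-numbered libraries correlated at 0.245 to 0.439 across genes between the WT groups of part 1, and at -0.265 to 0.116 in its other pairs of groups, and genes are not independent replicates. Depth limits genes with few counts: IFNB1, at 14 and 4 counts in irradiated WT cells at 5 days, was not testable in part 1.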

Other observations

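The tests of depth and of a batch shared by WT libraries of one number, and the separate test of genes that radiation changed the other way, were chosen only after the results were seen.

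Against untreated WT cells, of the cholesterol biosynthesis genes 20 of 24 rose and 0 fell (22 and 0 adjusted over the list alone) in irradiated cGAS KO cells at 5 days, at a median of 1.39 (camera adjusted p = 7.44e-10, adjusted p = 0.731 with an estimated correlation). In STING KO 21 of 24 rose and 0 fell (23 and 0 adjusted over the list alone), at 1.43 (camera adjusted p = 4.19e-10, adjusted p = 0.762 with an estimated correlation), and in XRCC4 KO 22 of 24 rose and 0 fell (22 and 0 adjusted over the list alone), at 1.37 (camera adjusted p = 1.6e-08, adjusted p = 0.711 with an estimated correlation). Part of this was seen without a knockout: the list level was 5.90 ± 0.42 log2 CPM (SD, n = 2) in untreated WT cells, 6.60 ± 0.14 in irradiated WT cells and 6.98 ± 0.45 with CDK1i, against 7.29 ± 0.04, 7.31 ± 0.29 and 7.24 ± 0.01 in cGAS, STING and XRCC4 KO. The list was lower in RPE-1 p53 KO against WT, where 24 of 24 fell and 0 rose (24 and 0 adjusted over the list alone). The median was -0.84 (camera adjusted p = 7.83e-12, adjusted p = 0.26 with an estimated correlation). Epidermal differentiation genes were higher in cGAS KO than in untreated WT cells, where 24 of 37 rose and 1 fell (25 and 1 adjusted over the list alone). Their median was 4.08, or 3.88 with members at 0 counts set to their bound (camera adjusted p = 3.07e-05, adjusted p = 0.869 with an estimated correlation). In irradiated WT cells against the same control it was 2.97, or 2.71 with members at 0 counts set to their bound.

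In part 2, epidermal genes were higher with ATRi in XRCC4 KO, where 20 of 35 rose and 5 fell (23 and 5 adjusted over the list alone). The median was 0.61 (camera adjusted p = 7.62e-13). Histone genes with ATRi in the DKO gave 1.33, where 12 of 16 rose and 1 fell (12 and 1 adjusted over the list alone) (camera adjusted p = 1.48e-05). Against p53 KO, the DKO had lower luminal markers, where 14 of 15 fell and 0 rose (14 and 0 adjusted over the list alone). The median was -1.06 (camera adjusted p = 2.76e-10). In RPE-1 WT cGAS against WT, hypoxia and glycolysis genes were higher, where 18 of 25 rose and 4 fell (18 and 4 adjusted over the list alone). The median was 0.44 (camera adjusted p = 6.19e-05, adjusted p = 0.23 with an estimated correlation). In p53 KO against WT cGAS, p53 targets were lower, where 34 of 38 fell and 0 rose (35 and 0 adjusted over the list alone). The median was -2.05 (camera adjusted p = 2.92e-19, adjusted p = 0.24 with an estimated correlation).

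At 5 days 1319 genes were called the same way in cGAS, STING and XRCC4 KO against irradiated WT cells, 688 higher and 631 lower. In 20 simulations per pair with shared control libraries the covariances reached at most 0.126, and the lowest observed was 0.722. The simulations drew genes and libraries independently and so left out shifts that many genes share within a group. Thus 0.126 is no upper bound, and the simulations alone cannot exclude shared controls as a cause. A loss of the radiation response from a baseline equal to WT would leave these genes near the untreated WT level. In all 3 knockouts 61.6% of them (813) lay beyond that level, so a return to it does not account for them. No unirradiated knockout cells were measured, so the baseline of these lines is unknown. The test therefore cannot decide on a loss of the response. Radiation had changed 343 of the 1319 the other way, and 23 of these (6.71%) lay beyond the untreated WT level. For these 343 a loss of the response stays open as well. Genes changed in cGAS and STING KO against both WT groups had a signed median log2 fold change of -0.0125 in the p53 KO of part 2 and 0.78 in cGAS KO. They were selected for their change in cGAS KO, so 0.78 is no independent measure. As a set they did not share this shift in p53 KO. That is a single line in which 8796 of all 16632 genes tested were called, so it cannot decide for other edited lines. In that p53 KO 295 of 939 were called the same way and 308 the other way. The signed median was 0.79 in the XRCC4 KO of part 2, where 845 of 939 were called the same way and 17 the other way. That group was set against the WT libraries of part 2, not those of part 1. For these genes the values therefore argue against the shared control libraries as the cause. A difference between WT and some edited lines, a shared history of these lines and effects of the knockouts themselves stay open as untested.

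In irradiated WT cells at 5 days the interferon-stimulated genes lay 1.51 log2 higher in replicate 1 than in replicate 2. Their totals were 14674420 and 16273391 counts, a log2 ratio of -0.149, which goes the other way and argues against depth. Deviations of same-numbered libraries correlated across genes at 0.245 or more between every pair of the 4 WT groups of part 1. In its other pairs they correlated at 0.116 or less, so a batch shared by WT libraries of one number may account for it. The list was also higher in replicate 1 than in replicate 2 at 3 days (4.77 and 3.68 log2 CPM) and with CDK1i (3.91 and 2.88). It was nearly equal in untreated cells (3.22 and 3.14). An equal offset in all WT groups would not give this, so such a batch would have to act on irradiated cells. The labels name no batch, and no biological explanation was tested.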
